A study of Homo sapiens with 60 samples.

How the data were processed

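RNA was sequenced from 60 cultures of U2OS, an established human osteosarcoma cell line, that carried an engineered PERK. PERK, the product of EIF2AK3, is a kinase of the endoplasmic reticulum that phosphorylates the translation initiation factor eIF2 alpha and so starts the integrated stress response (ISR), a program in which protein synthesis falls and the transcription factor ATF4 is made. Per the labels, the kinase domain was fused to a domain that dimerizes when the small molecule AP20187 is added, so that the dose and the duration of the drug set the strength and the length of the signal without other stress. Cells were treated at 0.01, 0.195 or 3 nM, at 6 times from 1 to 24 h, with 3 replicates in each of the 18 combinations, and 2 sets of 3 untreated libraries were labelled 0 h. The middle dose is 0.195 nM in the sample labels and is rounded to 0.2 nM in the text and figures. Per the labels, cells were seeded a day before treatment and the drug was added at different times before collection, and no untreated culture was handled in parallel at each time. Total RNA was extracted from wells of a plate and made into strand-specific libraries for an Illumina NovaSeq, per the labels' protocols.

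The authors deposited 1 table of estimated counts per gene and 1 table of TPM per gene (transcript abundance corrected for length and scaled to a fixed total), which also paired gene identifiers with symbols. Salmon 0.9.1, FastQC 0.11.5 and the genome build GRCh38 were named in the submitters' processing notes, which did not state their roles here. The annotation release was not given in the sources used here. Of the 57665 deposited genes, 57068 (99%) matched an identifier in GENCODE release 29, from which positions on GRCh38 were taken. Across the deposited counts, 54.2% of the estimated counts were whole within 1e-06, and all were rounded to whole numbers before use. No gene in the table lacked a name, and no column belonged to a sample outside the series. Reads that fit several near-identical genes are shared by estimation in such counts, so values of repeat families, pseudogenes and short structural RNAs are uncertain.

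Total counts per library ran from 5598803 to 28436445. The libraries fell into a shallow set (untreated set 1, 0.01 nM and 0.195 nM; 39 libraries, 5598803 to 10367667 counts) and a deep set (untreated set 2 and 3 nM; 21 libraries, 20713981 to 28436445 counts), a ratio of medians of 3.19. The labels did not tie an untreated set to a dose. A count of 0 in 1 library allowed up to 3 counts, which is 0.536 CPM (counts scaled to a fixed library total) at the lowest depth of the shallow set and 0.145 CPM in the deep set. Reads carried no molecular identifiers, so intervals and floors cover counting error only. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is given as a lower bound, and with 1 to 3 counts the ratio is given with its exact 95% counting interval. Against untreated, such folds pooled the counts of both untreated sets, so the deeper set 2 weighs more than in the tests described below.

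Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after TMM scaling and filterByExpr, which kept 18040 genes. All 60 libraries entered 1 fit with a mean for each of the 20 groups and no other covariate, which left 40 residual degrees of freedom. The control was the mean of both untreated set means. The 35 contrasts were each dose and time against untreated (18), adjacent doses at the same time (12), 24 h against 4 h within each dose (3), untreated set 2 against set 1, and the difference between 3 and 0.195 nM in the change from 4 to 24 h. P-values were adjusted within each contrast by the Benjamini-Hochberg method, genes were called at an adjusted p under 0.05, and the number with at least a 2-fold change is given beside the number called. Where a standard error (SE) of a log2 fold change is given, it is the value implied by the test. It is the size of the change divided by the square root of its F statistic, and so is approximate. There were n = 3 libraries per group throughout (6 untreated). Replicates were separate samples in the labels, which did not say whether they were separate cultures. P-values therefore measure only the spread between these samples, which may be technical. That spread was small: over genes above 20 CPM the median coefficient of variation in a group was 2.68% to 5.3%. The mean expected from counting alone is 2.54% to 5.12%. A median of variances from 3 libraries lies below their mean, so setting these ranges side by side understates the spread beyond counting. The common dispersion was 0.00129 and the median trended dispersion 0.00218, so differences of a few percent pass the test, and the size of a change carries more than its p-value. Between replicates, chi-square per degree of freedom ran from 1.371 to 21.86, so no pair of libraries differed by sampling noise alone and each counted as 1 sample.

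The 31 gene lists were core ISR genes, ISR regulators, amino acid synthesis and transport, cytosolic tRNA synthetases, secreted stress factors, endoplasmic reticulum (ER) chaperones and ER-associated degradation, heat shock, NRF2 targets, p53 targets, cell death and survival, cholesterol synthesis and uptake, S phase and DNA replication, G2 and mitosis, replication-dependent histones, ribosomal proteins, ribosome biogenesis, snoRNA host genes, translation initiation factors, eIF2 alpha kinases and phosphatase subunits, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, mitochondrial chaperones and proteases, immediate early genes, NF-kB and inflammatory genes, interferon-stimulated genes, hypoxia and glycolysis, autophagy and lysosome, extracellular matrix, and markers of epithelial, endothelial, and blood and immune cells as other cell types. Each was tested, except the blood and immune markers, of which only 1 was expressed enough to test, with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, on log2 CPM with the same groups, and p-values were adjusted over lists and contrasts within 3 families. In 45 of 180 list results against untreated at 4 and 24 h the call was lost with the estimated correlation. Each list is given as members called higher and lower among those tested, followed by the count adjusted over the list alone where it differed.

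Samples were grouped by the labels' dose and time. The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule named the 20 core ISR genes, the 8 genes with the largest rise and the 8 with the largest fall at 4 and at 24 h of each dose against untreated, 5 of each kind for both dose steps at 24 h, for 24 against 4 h within each dose and for the untreated sets, all among called genes above 1 in mean log2 CPM whose libraries did not overlap between the groups, and up to 4 members with the smallest p for each list described. Genes of unknown function and repeat copies are named less often than the rule allows. The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 0.5, the replicate number as a block, each library left out in turn, only the compared libraries in the fit, either untreated set alone as control, and each dose relative to 1 untreated set for 3 against 0.195 nM. One more, chosen after seeing the data, thinned the deep libraries at random to the median depth of the others. The method was tested on simulated data for 3 nM at 4 h against untreated, with 79, 82 and 64 genes changed 1.5-fold, 2-fold and 4-fold among 17344 tested and a median trended dispersion of 0.00218. There 83.5% of genes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 4-fold were called, with 11 calls among 17119 unchanged genes. All simulated libraries were drawn from the pooled untreated profile, so the simulation held no difference between sets of libraries. Its rate of false calls does not cover a difference such as that between the untreated sets. The changed genes were few and were drawn only from genes above a minimum expected count in the shallowest library. The simulation thus tested neither the scaling when most genes change nor recovery at low counts.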

Results

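The series measured the RNA of U2OS cells in which an engineered PERK was switched on with the dimerizer AP20187 at 0.01, 0.2 or 3 nM for 6 lengths of time from 1 to 24 h. Each of the 18 combinations had 3 libraries, and 6 libraries were untreated, in 2 sets of 3. Per the labels, the low dose was chosen for little loss of protein synthesis, the middle dose for a partial loss and the high dose for the strongest loss. Total counts were 5598803 to 10367667 in untreated set 1 and at 0.01 and 0.2 nM, and 20713981 to 28436445 in untreated set 2 and at 3 nM. Mitochondrially encoded mRNAs took 8.84% ± 0.62 of the counts in untreated set 1 (SD, n = 3), 4.44% ± 0.051 in untreated set 2, 4.75% ± 0.046 at 0.01 nM, 4.28% ± 0.072 at 0.2 nM and 3.4% ± 0.015 at 3 nM after 24 h. Because 0.01 and 0.2 nM share the depth of set 1, and 3 nM that of set 2, values against the set of like depth are given beside those against both for the numbers of genes called and for most gene lists, but for few single genes. No untreated culture was handled in parallel at each time, so an effect of the addition itself, or of time since it, cannot be separated from that of the drug.

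The first question was which genes the strongest dose moved. At 3 nM, 19 of the 20 core genes of the integrated stress response were higher after 24 h than without drug, and 1, ATF3, was lower (median log2 fold change 1.77, and 1.97 against untreated set 2, camera adjusted p = 2.4e-11). ATF4, the transcription factor at the centre of the response (chromosome 22, 39519695 to 39522685), rose from 293 ± 7.69 CPM (SD, n = 3) in untreated set 2 to 731 ± 6.25 (log2 fold change 1.16 against both sets). ASNS, which makes asparagine (chromosome 7, 97852118 to 97872542), rose from 51.3 ± 0.948 to 445 ± 2.63 CPM (log2 fold change 3.16, SE 0.0437, edgeR adjusted p = 3.1e-53). TRIB3, a pseudokinase that restrains ATF4, rose by 4.49 (SE 0.0553, edgeR adjusted p = 2e-55), CHAC1, which breaks down glutathione, by 4.08, and SLC7A11, the cystine transporter, by 3.64. DDIT3, the transcription factor CHOP, rose by 1.84, and PPP1R15A, the phosphatase subunit that reverses eIF2 alpha phosphorylation, by 1.87. EIF2AK3, the gene of PERK itself, rose by 0.91, but reads from the engineered kinase domain, which per the labels is of mouse origin, may be counted there and cannot be told apart.

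**Figure D1:**
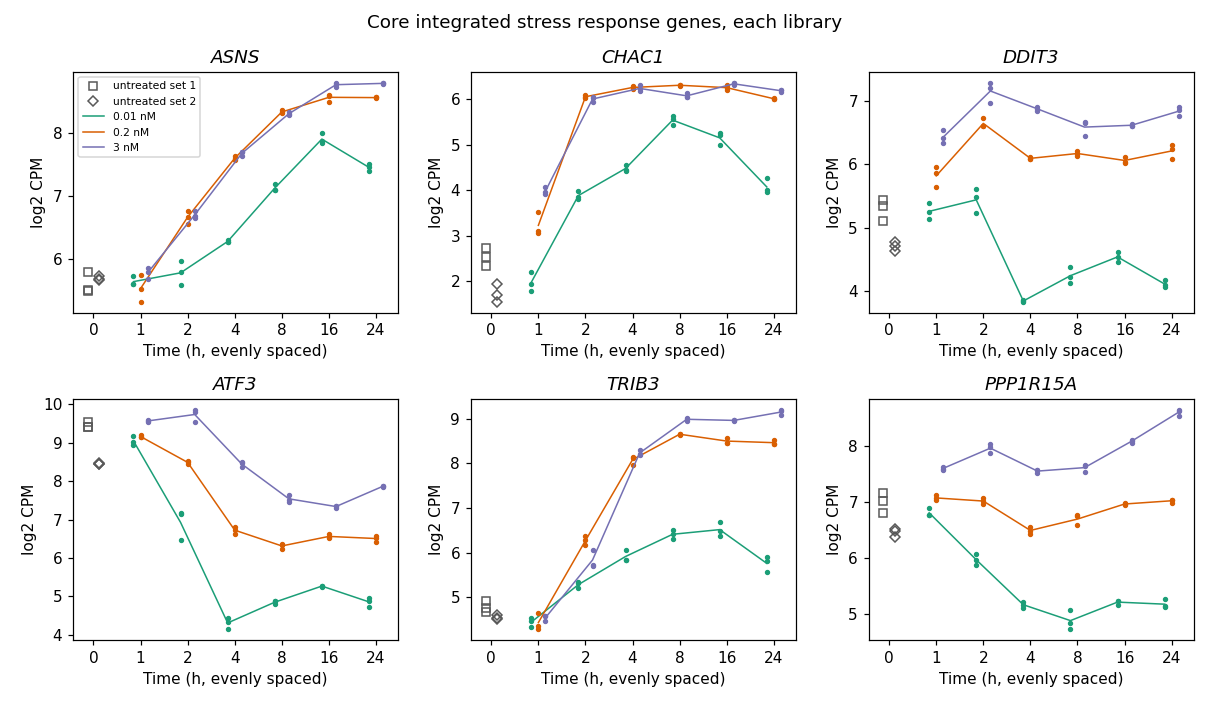
Normalised level (log2 CPM) of core genes of the integrated stress response in each library, by time after drug addition and by dose, with the untreated libraries at 0 h. Points are libraries and lines join group means; ASNS rose to a log2 fold change of 1.82, 2.93 and 3.16 after 24 h at 0.01, 0.2 and 3 nM.

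The order of these changes differed between genes at 3 nM. After 1 h DDIT3 was higher by 1.43 and CHAC1 by 1.87, while ASNS differed by 0.13 and TRIB3 by -0.13. After 4 h 18 core genes had risen and 2 had fallen (median 1.46, and 1.64 against untreated set 2, camera adjusted p = 1.6e-13). DDIT4, an inhibitor of mTORC1 signalling, stood highest at 4 h (3.57) and was lower by 0.95 from 4 to 24 h. FGF21, a secreted stress hormone, rose by 4.13 at 4 h and 4.38 at 24 h. ATF3, a stress-induced transcription factor, fell by 0.51 at 4 h against both untreated sets but differed by only -0.02 from untreated set 2 (adjusted p = 0.856).

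Genes for making and importing amino acids rose together at 3 nM. After 24 h 21 of 22 were higher and 1 lower (median log2 fold change 1.95, and 1.97 against untreated set 2, camera adjusted p = 1.5e-13), among them CTH, which makes cysteine, by 3.83 and MTHFD2, of the mitochondrial folate pathway, by 2.71. Of the cytosolic tRNA synthetases, which load amino acids onto tRNA, 19 of 20 rose and 1 fell (median 1.61 against either control, adjusted p = 1.9e-12), with WARS at 2.95 and GARS at 2.33. All 27 ribosome biogenesis genes rose (median 1.43, and 1.45 against untreated set 2, adjusted p = 1.6e-16), for example RRP12 by 2.17 and DDX21 by 1.90. All 21 translation initiation factors rose (0.88, and 0.82 against set 2, adjusted p = 4.3e-10), and EIF4EBP1, a brake on cap-dependent translation in the same list, rose by 2.19. All 15 host genes of small nucleolar RNAs rose (1.5, and 1.29 against set 2, adjusted p = 1.3e-08), such as ZFAS1 by 2.69 and GAS5 by 2.48, both short transcripts known to be degraded when they are translated. Of 13 mitochondrial chaperones and proteases, 11 rose and 1 fell (0.79, and 0.776 against set 2, adjusted p = 2.9e-05). The protease gene LONP1 was at 1.83. Of 11 secreted stress factors, 10 rose and 1 fell (1.70, and 1.80 against set 2, adjusted p = 0.0012), including the cytokine TSLP by 5.81 and INHBE by 3.39. Of 16 ISR regulators, 12 rose and 3 fell (1.26, and 1.42 against set 2, adjusted p = 5.2e-05), and CEBPG, a partner of ATF4, rose by 2.39.

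Other families fell at 3 nM after 24 h. Of 18 extracellular matrix genes 17 fell and 1 rose (median log2 fold change -1.71, and -1.65 against untreated set 2, camera adjusted p = 4.6e-10), and COL1A1, a chain of type I collagen, fell by 3.07, THBS1 by 3.65 and SPARC by 2.18. Of 23 genes of cholesterol synthesis and uptake 22 fell and none rose (-1.22, and -1.27 against set 2, adjusted p = 2.3e-11), with INSIG1, a target and brake of the sterol factor SREBP2, at -3.28. All 8 tested replication-dependent histone genes fell (-2.08, and -2.00 against set 2, adjusted p = 0.0013), as did 13 of 15 interferon-stimulated genes against 1 that rose (-1.28, and -1.22 against set 2, adjusted p = 0.0011), such as IFI6 by 3.15 and IFIT1 by 4.48. Of 17 immediate early genes, the fast targets of growth signals, 15 fell and 2 rose (-2.22, and -2.08 against set 2, adjusted p = 1.2e-09), with the transcription factor gene EGR2 at -7.75 and the nuclear receptor gene NR4A1 at -4.57. The 13 mitochondrially encoded mRNAs all fell against both sets (-0.84, adjusted p = 4.7e-09), but their median was only -0.30 against untreated set 2, where MT-CO2 was at -0.42 and MT-CYB at -0.30, and the adjusted p was 0.0611 with an estimated correlation. Of 25 G2 and mitosis genes 20 fell and 2 rose (-0.28, and -0.347 against set 2, adjusted p = 0.00383), with KIF20A, a mitotic motor, at -1.87, and the adjusted p was 0.468 with an estimated correlation. Of 21 hypoxia and glycolysis genes 14 fell and 5 rose (-0.42, adjusted p = 0.0335, and 0.234 as the adjusted p with an estimated correlation); against set 2 alone the list missed the threshold (-0.33, adjusted p = 0.107), and HK2, the first enzyme of glycolysis, rose by 3.04.

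The other lists did not pass the test at 3 nM after 24 h. Among 23 chaperones and degradation factors of the endoplasmic reticulum 12 were higher and 7 lower (median 0.13, and 0.35 against untreated set 2, camera adjusted p = 0.339), and XBP1, a transcription factor of the unfolded protein response, rose by 1.92 and HSPA5, its main chaperone, by 1.13. The 75 ribosomal protein genes split into 38 higher and 19 lower, or 39 and 19 adjusted over the list alone (0.092, adjusted p = 0.117); against untreated set 2 alone the list was higher (0.16, adjusted p = 0.00251). Of 18 NF-kB and inflammatory genes 11 were higher and 5 lower (0.51, and 0.71 against set 2, adjusted p = 0.248). For 16 heat shock genes, 7 higher and 8 lower, the median was 0.043 (-0.0598 against set 2), the mean -0.33 and the median on the TPM scale -0.026 (adjusted p = 0.296); CRYAB, a small heat shock protein, fell by 3.25. For 20 NRF2 targets, 9 higher and 8 lower, the median was -0.024 (0.00855 against set 2), the mean 0.27 and the median on the TPM scale 0.078 (adjusted p = 0.765). For 16 cell death genes, 10 higher and 5 lower, the median was 0.21 (0.301 against set 2) and the mean -0.071 (adjusted p = 0.409), with the death receptor gene TNFRSF10B at 1.51 and BMF, a BCL2 antagonist, at -6.01. Of 19 p53 targets 8 were higher and 10 lower (-0.24, adjusted p = 0.105), and the list passed the test, as lower, against untreated set 1 alone (-0.48, adjusted p = 0.0306). The medians were 0.034 for 23 S phase genes (11 higher, 6 lower, adjusted p = 0.513), 0.14 for 6 eIF2 alpha kinases and phosphatase subunits (4 and 2, adjusted p = 0.246), -0.13 for 27 nuclear-encoded respiratory chain genes (8 and 15, adjusted p = 0.259) and -0.097 for 21 autophagy and lysosome genes (9 and 11, adjusted p = 0.441). Markers of other cell types were tested too: 7 epithelial markers had 2 higher and 4 lower (-0.57, adjusted p = 0.315) and 5 endothelial markers 2 and 2 (-0.39, but 0.38 on the TPM scale, adjusted p = 0.637). Of the blood and immune markers only CD68, a lysosomal membrane protein, was tested, and it rose by 2.83.

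Among the largest changes at 3 nM after 24 h, SPRR2D, a cornified envelope gene, rose 1450-fold (95% counting interval 260 to 57500) to 15.2 ± 0.346 CPM, INSC, which orients dividing cells, by 8.47 on the log2 scale (6.56 against untreated set 2 and 10.38 against set 1), KLHDC7B 235-fold (interval 80.1 to 1140) and ESRP1, an epithelial splicing factor, by 6.18 on the log2 scale. DRD1, a dopamine receptor gene, was 931-fold lower (interval 318 to 4520) and the muscle gene SLN at least 89.5-fold lower. These folds pool the counts of both untreated sets. Against the mean of both set means the fitted folds were 667 for SPRR2D, 164 for KLHDC7B and 750 for DRD1. IGFBP5, which binds insulin-like growth factors, fell from 254 ± 11.1 CPM in untreated set 2 to 0.48 ± 0.162 (log2 fold change -9.32, SE 0.159, edgeR adjusted p = 7.7e-49). The chemokine CXCL14 fell by 7.70. The long noncoding RNA MIAT was at -7.41 and OLFML2A at -7.31. KRT14, a keratin, fell by 5.62 (6.51 without replicate 2 of the treated group).

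After 4 h at 3 nM all 18 tested NF-kB and inflammatory genes were higher (median log2 fold change 2.38, and 2.37 against untreated set 2, camera adjusted p = 3.7e-11), including TRAF1, an adaptor of TNF receptors, by 4.73, the chemokine CXCL8 by 4.20, RELB by 2.95 and NFKB1 by 2.73. Heat shock genes fell (2 higher and 10 lower of 16, -0.24, and -0.18 against set 2, adjusted p = 0.000129, and 0.098 as the adjusted p with an estimated correlation). HSPA1A, the inducible HSP70, was at -3.12. Secreted stress factors rose (10 higher and 1 lower of 11, 2.37, and 2.39 against set 2, adjusted p = 7.5e-08), including IL11 by 2.48, and matrix genes fell less than at 24 h (1 higher and 14 lower of 18, -0.33, and -0.19 against set 2, adjusted p = 0.00134, and 0.113 as the adjusted p with an estimated correlation). Immediate early genes fell (1 higher and 16 lower of 17, -1.14, and -1.04 against set 2, adjusted p = 3.3e-10), with FOSB at -3.96 (-2.48 against set 2 and -5.44 against set 1). BMF fell by 4.11, BMP4, a growth factor of bone and embryo, by 3.24 and RNF43, which limits Wnt signalling, by 3.11. The short structural RNAs RNA5-8S5, RNA5S1 and RMRP were also among the largest rises (4.65, 4.85 and 4.80), and fell to 3.19, 3.40 and 4.04 without replicate 1 of the treated group, whose RNA5-8S5 stood at 1340 CPM against 204 and 230 in the others.

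At 3 nM the number of genes called rose with time, from 7876 after 1 h to 9108, 12053, 13081, 13729 and 13913 after 2, 4, 8, 16 and 24 h, of 18040 tested (edgeR, Benjamini-Hochberg). Of these, 228 were at least 2-fold higher and 43 lower after 1 h, and 1889 higher and 2961 lower after 24 h. Against untreated set 2 these numbers were 59 and 14 after 1 h and 1664 and 3095 after 24 h, and against set 1 they were 804 and 150, and 2231 and 2953, so the number after 1 h depends on the control. Against untreated set 2 alone 4843, 7559, 11499, 12771, 13604 and 13693 were called. After 1 h 4082 were higher and 3794 lower on counts, but 4784 and 395 with limma on TPM; the TPM splits at 2, 4 and 8 h were 4393 and 1130, 5425 and 3273, and 6899 and 3684, against 4939 and 4169, 6291 and 5762, and 6942 and 6139 on counts. TPM moved the median of all genes against untreated by 0.0245 to 0.174 on the log2 scale, and by 0.16 in this comparison after 1 h, so directions on that scale are relative to that shift.

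**Figure D2:**
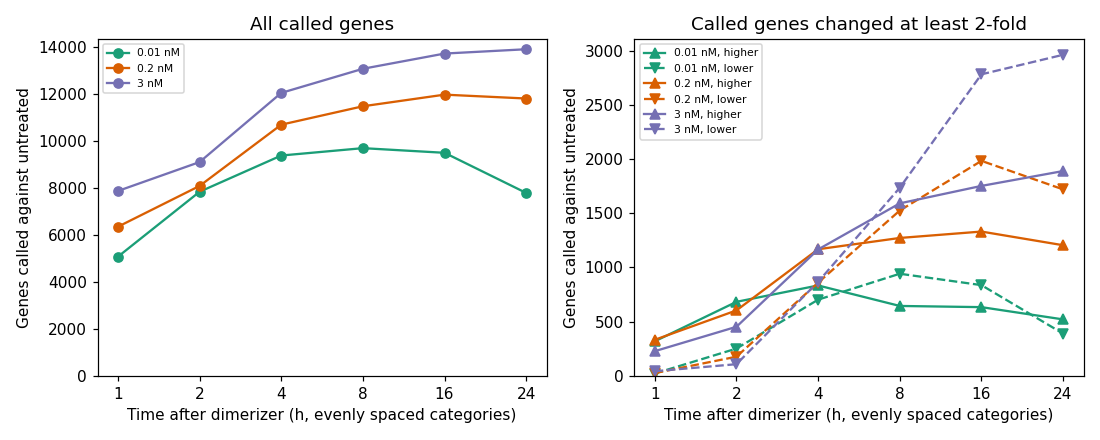
Left, number of genes called against untreated in either direction (edgeR, Benjamini-Hochberg adjusted p under 0.05, 18040 genes tested) at each dose and time. Right, number of called genes at least 2-fold higher or lower. Calls reached 9700 at 0.01 nM, 11979 at 0.2 nM and 13913 at 3 nM. The 3 nM libraries were deeper, so smaller changes can be called there and these numbers do not compare doses alone. After 1 h 0.01, 0.2 and 3 nM had 5077, 6353 and 7876 calls, but 341, 359 and 271 at least 2-fold. After 24 h those at least 2-fold numbered 911, 2925 and 4850.

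The middle dose addressed a partial block of protein synthesis. At 0.2 nM 19 core genes were higher and 1, ATF3, lower than untreated after 24 h (median log2 fold change 1.36, and 1.19 against untreated set 1, camera adjusted p = 2e-14). ASNS reached 380 ± 2.63 CPM (SD, n = 3; log2 fold change 2.93, SE 0.0459, edgeR adjusted p = 8.3e-50), TRIB3 rose by 3.80, CHAC1 by 3.90 and FGF21 by 4.68. Amino acid genes rose (21 higher and 1 lower of 22, 1.81, and 1.75 against set 1, adjusted p = 2.4e-19), as did tRNA synthetases (17 and 1 of 20, 1.24, and 1.28 against set 1, adjusted p = 8.3e-14) and all 27 ribosome biogenesis genes (0.91, and 0.92 against set 1, adjusted p = 7.8e-18), with SLC1A5, a glutamine transporter, at 2.15 and MARS at 1.58. PPP1R15A rose by 0.29, but by only 0.03 against untreated set 1 (adjusted p = 0.717).

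Unlike at 3 nM, where the NF-kB list did not pass at 24 h, inflammatory genes fell at 0.2 nM after 24 h (4 higher and 12 lower of 18, median -1.41, and -1.73 against untreated set 1, camera adjusted p = 0.00264, and 0.139 as the adjusted p with an estimated correlation). CCL2, which attracts monocytes, fell by 4.55, CXCL8 by 2.84 and NFKBIA, the inhibitor of NF-kB, by 2.27, and the cytokine genes CSF2 and TNF, with no count in the 3 treated libraries, were at least 24.9-fold and 13.4-fold lower. All 17 immediate early genes fell (-3.07, and -3.52 against set 1, adjusted p = 5.2e-18), and EGR4 was 153-fold lower (95% counting interval 52.2 to 742). Cholesterol genes fell (none higher and 22 lower of 23, -1.09, and -1.06 against set 1, adjusted p = 4.9e-16), and interferon-stimulated genes fell (1 higher and 12 lower of 15, or 13 lower adjusted over the list alone, -1.11, and -1.02 against set 1, adjusted p = 0.00201). G2 and mitosis genes fell (none higher and 23 lower of 25, or 24 adjusted over the list alone, -0.35, and -0.27 against set 1, adjusted p = 6.2e-06, and 0.234 as the adjusted p with an estimated correlation). ESRP1 rose by 6.76, SPX, a secreted peptide gene, by 5.09 and KLHDC7B 280-fold (interval 94.6 to 1370), and CXCL14 fell by 5.92.

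After 4 h at 0.2 nM inflammatory genes were higher (13 higher and 3 lower of 18, median 1.47, and 1.33 against untreated set 1, camera adjusted p = 2.2e-05), with TRAF1 at 4.34, BIRC3, an inhibitor of apoptosis, at 3.33 and NFKB1 at 2.23. Of 20 core genes 16 rose and 3 fell (1.20, and 1.00 against set 1, adjusted p = 2.1e-11), and amino acid genes rose (21 higher, none lower of 22, 1.78, and 1.76 against set 1, adjusted p = 1.2e-21). GPT2 was at 2.29. Immediate early genes fell (1 higher and 16 lower of 17, -1.94, and -2.17 against set 1, adjusted p = 5.1e-17), with EGR1 at -3.47 and FOS at -3.95 (-5.42 against set 1 and -2.49 against set 2). Chaperones of the endoplasmic reticulum did not pass the test (9 higher and 6 lower of 23, 0.026, and -0.058 against set 1, adjusted p = 0.222), although HSPA5 rose by 0.79 and HERPUD1, a degradation factor, by 1.00. EIF2AK3 was higher by 0.12, and by 0.03 against set 2 alone (adjusted p = 0.374). The numbers called after 1, 2, 4, 8, 16 and 24 h were 6353, 8091, 10700, 11484, 11979 and 11814, or 6434, 7936, 10138, 10751, 11209 and 11026 against untreated set 1. Of them 2928, 4049, 5433, 5922, 6294 and 6191 were higher, and 3425, 4042, 5267, 5562, 5685 and 5623 lower, against 5212, 5639, 6585, 7046, 7122 and 6927 higher, and 453, 1228, 2645, 3363, 3831 and 3481 lower, with limma on TPM. At least 2-fold changes numbered 333 higher and 26 lower after 1 h and 1205 and 1720 after 24 h. They were 845 and 52, and 1565 and 1691, against untreated set 1, and 115 and 76, and 964 and 1833, against set 2, so the number after 1 h depends on the control.

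The low dose asked what a signal with little loss of protein synthesis does. At 0.01 nM ASNS rose from 48.4 ± 5.93 CPM in untreated set 1 to 176 ± 7.59 after 24 h (SD, n = 3; log2 fold change 1.82, SE 0.0509, edgeR adjusted p = 7.9e-37), SLC7A11 by 1.87 and PHGDH, the first enzyme of serine synthesis, by 1.19. Against untreated, DDIT3 was lower by 0.90, PPP1R15A by 1.56 and ATF3 by 4.10. After 24 h at the middle and high doses DDIT3 was at 1.21 and 1.84, PPP1R15A at 0.29 and 1.87, and ATF3 at -2.45 and -1.09. Each thus stood higher at the higher doses. Handling around drug addition or the untreated collection, left open below for immediate early genes, was not tested for these genes. Their fall can therefore not be assigned to the low dose. Of 20 core genes 13 were higher and 7 lower (median 0.35, and 0.34 against untreated set 1, camera adjusted p = 0.000259). Amino acid genes rose (19 higher and 2 lower of 22, 0.96, and 0.94 against set 1, adjusted p = 5.9e-23), and all 25 G2 and mitosis genes were higher (0.47, and 0.53 against set 1, adjusted p = 3.7e-18), among them CENPF by 0.58 and MKI67, a proliferation marker, by 0.60.

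All 17 immediate early genes fell at 0.01 nM after 24 h (median -2.98, and -3.20 against untreated set 1, camera adjusted p = 1e-43), with NR4A1 at -4.87 and CYR61 at -2.98, and no inflammatory gene rose while 16 of 18 fell (-2.24, and -2.44 against set 1, adjusted p = 1.3e-15), with CXCL8 at -5.22 and TNFAIP3, a feedback inhibitor, at -3.49. The chemokine CCL4 was 80.4-fold lower (95% counting interval 14.3 to 3180). Cholesterol genes fell (1 higher and 21 lower of 23, -0.63, and -0.58 against set 1, adjusted p = 4.6e-19). HMGCS1 was at -1.23. Chaperones of the endoplasmic reticulum were slightly lower (none higher and 12 lower of 23, -0.11, and -0.26 against set 1, adjusted p = 0.00024, and 0.0839 as the adjusted p with an estimated correlation), but the median was -0.021 against set 2 alone (adjusted p = 0.523) and 0.052 on the TPM scale, or -0.091 relative to all genes; HSPA5 was lower by 0.22, and by 0.06 against set 2 alone (adjusted p = 0.205). FGF21 rose by 3.17, the protease gene PAPPA2 by 2.67 and KLHDC7B 45.6-fold (interval 14.4 to 231).

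After 4 h at 0.01 nM the same chaperones were higher (20 higher, none lower of 23, median 0.34, and 0.30 against untreated set 1, camera adjusted p = 3.3e-10), with HSPA5 at 1.12 and MANF, a secreted protective factor, at 0.80. All 25 G2 and mitosis genes were lower (-0.69, and -0.60 against set 1, adjusted p = 1.1e-18). KIF11, a spindle motor, was at -0.93. All 17 immediate early genes fell (-2.09, and -2.47 against set 1, adjusted p = 4.4e-27), with EGR1 at -5.44, EGR2 at -8.20 and FOSB at -6.30 (-7.78 against set 1 and -4.81 against set 2). Amino acid genes rose (20 higher and 1 lower of 22, 0.57, and 0.50 against set 1, adjusted p = 2.2e-13). SLC7A5, a leucine transporter, was at 1.29. Secreted stress factors rose (7 higher and 2 lower of 11, 0.59, and 0.64 against set 1, adjusted p = 0.00312). IL11 was at 1.96. The NF-kB list did not pass the test (10 higher and 5 lower of 18, 0.41, and 0.37 against set 1, adjusted p = 0.0536), with BIRC3 at 2.62 and NFKBIA at -1.46. Of 20 core genes 13 rose and 4 fell (0.37, and 0.21 against set 1, adjusted p = 0.00297, and 0.101 as the adjusted p with an estimated correlation); SESN2, an inhibitor of mTORC1, rose by 0.39, but by 0.12 against set 1 alone (adjusted p = 0.133). PCDH7, a protocadherin, rose by 3.52 and BCL2A1, a survival gene, by 3.57 (4.46 without replicate 1 of untreated set 1).

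At 0.01 nM 5077, 7843, 9386, 9700, 9502 and 7792 genes were called after 1, 2, 4, 8, 16 and 24 h, or 5111, 7622, 8791, 8851, 8615 and 7053 against untreated set 1. Of them 2274, 3877, 4676, 5012, 4844 and 3790 were higher, and 2803, 3966, 4710, 4688, 4658 and 4002 lower, against 3134, 4543, 5311, 5410, 5355 and 5188 higher, and 532, 1503, 2505, 2590, 2698 and 1419 lower, with limma on TPM. At least 2-fold changes numbered 319 higher and 22 lower after 1 h and 521 and 390 after 24 h. They were 718 and 24, and 879 and 390, against untreated set 1, and 116 and 81, and 281 and 506, against set 2, so after 24 h even the more frequent direction depends on the control.

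**Figure D3:**
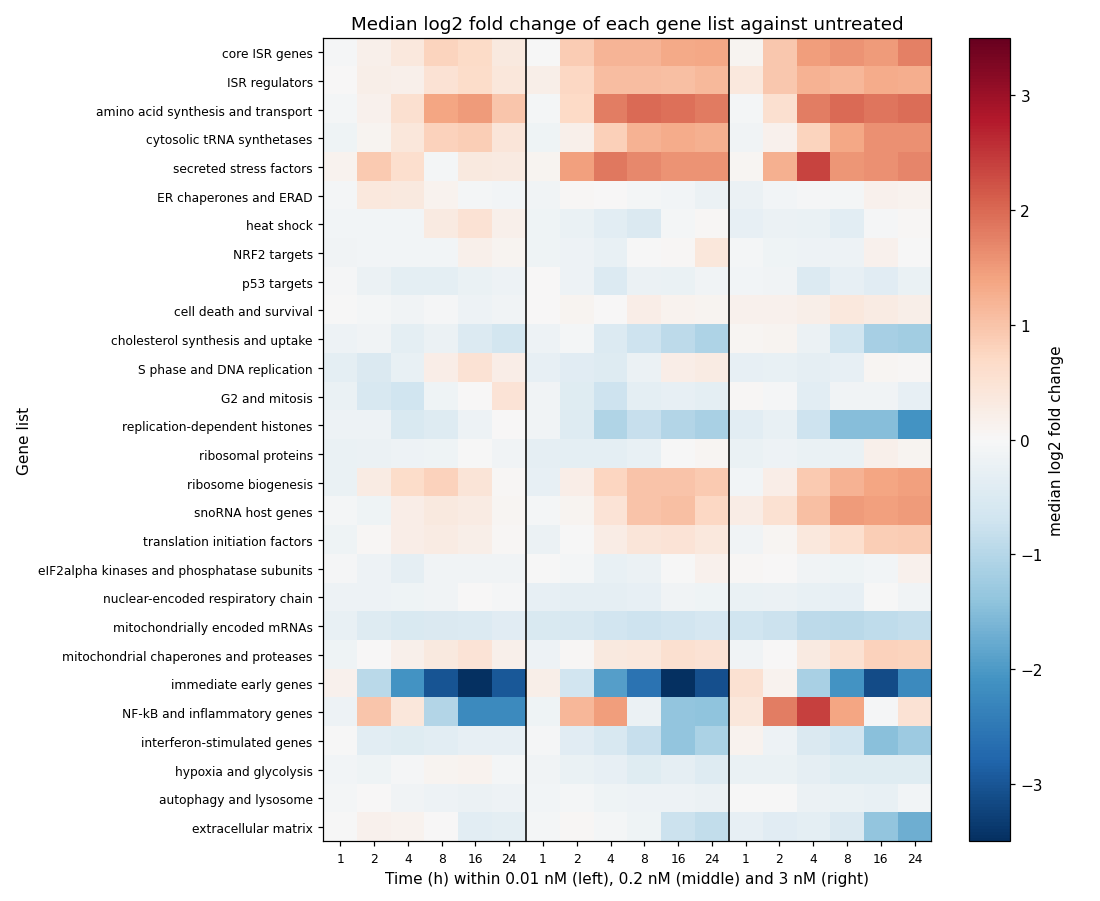
Median log2 fold change against untreated of each gene list, at each dose and time. The NF-kB and inflammatory list stood at 2.38 after 4 h and 0.51 after 24 h at 3 nM, and at 0.41 and -2.24 at 0.01 nM.

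Direct comparison of 3 with 0.2 nM showed what differed at the high dose, though it also sets deep against shallow libraries. After 24 h, 17 of 18 inflammatory genes were higher and 1 lower at 3 than at 0.2 nM (median log2 difference 2.40, or 2.15 with genes without counts at their bound, and 1.81 with each dose relative to its own untreated set, camera adjusted p = 4.8e-11), including CXCL8 by 5.03, BCL2A1 by 4.23 and TRAF1 by 3.34 (5.253, 4.083 and 2.573 with own sets), and TNF was at least 9.59-fold higher. No matrix gene was higher and 15 of 18 were lower (-0.77, adjusted p = 2.7e-10). COL1A1 was at -1.95, or -1.263 with own sets. The 8 histone genes had 6 lower, or 8 adjusted over the list alone (-1.18, adjusted p = 0.00232). HIST2H2BE was at -1.81 (-1.45 with own sets). Host genes of small nucleolar RNAs were higher (13 higher and 1 lower of 15, 0.70, adjusted p = 2.4e-06). SNHG17 was at 0.97 (0.729 with own sets). G2 and mitosis genes did not pass the test (8 higher and 4 lower of 25, 0.042 on counts and -0.028 on TPM, adjusted p = 0.619). Of 20 core genes 13 were higher and 3 lower, or 14 and 3 adjusted over the list alone (0.25, adjusted p = 0.000453, and 0.0624 as the adjusted p with an estimated correlation), led by PPP1R15A at 1.58, ATF3 at 1.36, TNFRSF10B at 0.85 and SESN2 at 0.74. With each dose relative to its own untreated set, PPP1R15A differed by 2.112, ATF3 by 2.352, TNFRSF10B by 0.939 and SESN2 by 1.286, but ASNS by 0.14 (adjusted p = 0.162) and SLC7A11 by 0.08 (adjusted p = 0.526). Where such a value exceeds the direct one, as for PPP1R15A and ATF3, untreated set 1 was higher than set 2. ATF3 stood at 9.407 to 9.536 log2 CPM in set 1 and 8.456 to 8.476 in set 2. PPP1R15A stood at 6.808 to 7.157 in set 1 and 6.384 to 6.527 in set 2. The gain is therefore no added evidence of a dose effect. IGFBP5 was lower by 4.40 (-3.795 with own sets), DRD1 41.1-fold (95% counting interval 13.3 to 206) and FOXS1 by 4.35 on the log2 scale (5.70 without replicate 1 at 3 nM, and -3.646 as the log2 difference with own sets). After 4 h ATF3 was higher at 3 nM by 1.72, PPP1R15A by 1.06 and DDIT3 by 0.78, or by 2.712, 1.589 and 1.383 with each dose relative to its own untreated set. The same limit applies to these gains, with DDIT3 at 5.105 to 5.434 log2 CPM in set 1 and 4.637 to 4.771 in set 2.

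Between 3 and 0.2 nM 4923, 6510, 6643, 6890, 8239 and 10125 genes were called after 1 to 24 h, of which 272 were at least 2-fold higher and 1191 lower after 24 h. This comparison sets deep against shallow libraries, whereas 0.2 and 0.01 nM share the shallow set. The 4923 after 1 h lie below the 5215 called between the untreated sets and cannot be set apart from such a difference. At least 2-fold, 180, 365, 374, 503, 713 and 1463 genes differed after 1 to 24 h, against 603 between the untreated sets. The later counts may hold such a difference in part. At 2, 4 and 16 h 3774, 3844 and 4844 were higher and 2736, 2799 and 3395 lower, against 1215, 1103 and 1729 higher and 1921, 2429 and 2862 lower with limma on TPM. With each dose relative to its own untreated set 2334, 4042, 4201 and 4586 were called after 1, 2, 4 and 8 h.

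All 20 core genes were higher at 0.2 than at 0.01 nM after 24 h (median log2 difference 1.29, camera adjusted p = 1.9e-19), with TRIB3 at 2.70 (SE 0.0702, edgeR adjusted p = 1e-37), PPP1R15A at 1.85 and VEGFA, an angiogenic factor, at 1.26. Amino acid genes were higher (21 higher and 1 lower of 22, 0.99, adjusted p = 2.8e-18), with MTHFD2 at 1.26, as were tRNA synthetases (19 and 1 of 20, 0.77, adjusted p = 5.6e-15). WARS was at 1.67. All 25 G2 and mitosis genes were lower (-0.84, adjusted p = 3.9e-19), with KIF20A at -1.48 and TOP2A at -0.87, and cholesterol genes were lower (none higher and 20 lower of 23, -0.57, adjusted p = 1.3e-10). Mitochondrially encoded mRNAs were lower by less (11 of 13, -0.14, adjusted p = 0.00552, and 0.398 as the adjusted p with an estimated correlation). MT-ND6 was at -0.31. OLAH, a thioesterase gene, was higher by 3.99 and SPRR2D 37.2-fold (95% counting interval 12.4 to 183), and IGFBP5 was lower by 4.13, RNF43 by 4.49 and ALPP, the placental alkaline phosphatase, by 4.36. The genes called numbered 137, 1784, 4324, 6626, 8095 and 9290 after 1 to 24 h. Of them 62, 997, 2460 and 3417 were higher and 75, 787, 1864 and 3209 lower after 1, 2, 4 and 8 h, against 184, 896, 2164 and 3133 higher and 36, 202, 884 and 1801 lower with limma on TPM, and 76 and 236 after 1 h with DESeq2. Without 1 library the count after 1 h ran from 50 (without replicate 3 at 0.01 nM) to 255 (without its replicate 1), and was 58 without its replicate 2 and 54, 88 and 78 without replicates 1, 2 and 3 at 0.2 nM.

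The change from 4 to 24 h was tested within each dose, and its difference between doses only for 3 against 0.2 nM. Inflammatory genes fell at all 3 doses: at 0.01 nM 15 of 18 fell and none rose (median log2 change -2.07, camera adjusted p = 4.4e-14), with CXCL8 at -5.53, at 0.2 nM 17 fell and none rose (-2.54, adjusted p = 1.8e-14), with CXCL8 at -5.44 and CSF2 at least 51.9-fold lower, and at 3 nM 17 fell and 1 rose (-1.34, adjusted p = 4.7e-07). Matrix genes also fell at all 3, with medians of -0.558, -1.09 and -1.58 (adjusted p = 9.6e-09, 2.3e-11 and 3.6e-11), and S phase genes rose, with 0.50, 0.73 and 0.411 (adjusted p = 4.3e-09, 9.6e-12 and 7.2e-05, and 0.135, 0.0834 and 0.341 as the adjusted p with an estimated correlation). At 0.01 nM all 25 G2 and mitosis genes rose (1.13, adjusted p = 2.9e-30), with BUB1, a spindle checkpoint kinase, at 1.5 and TPX2 at 1.34, and all 23 chaperones of the endoplasmic reticulum fell (-0.48, adjusted p = 5.7e-15), with HSPA5 at -1.34. Of the S phase genes PCNA was at 0.73. BMF rose by 3.38 and STC2, a secreted glycoprotein and ATF4 target, 15.9-fold (95% counting interval 4.13 to 136), and KRT34, a keratin, fell by 4.72. At 0.2 nM cholesterol genes fell (none higher and 19 lower of 23, or 20 adjusted over the list alone, -0.59, adjusted p = 2.6e-10). HMGCS1 was at -1.47. Ribosome biogenesis genes did not pass the test there (11 higher and 10 lower of 27, median -0.039 and mean 0.045, adjusted p = 0.485), whereas at 3 nM 26 rose and none fell (0.43, adjusted p = 2.5e-08, and 0.0998 as the adjusted p with an estimated correlation). BOP1 was at 0.96. At 3 nM the matrix gene THBS1 was at -3.27. Interferon-stimulated genes (1 higher and 11 lower of 15, -0.77, adjusted p = 0.0127) and cholesterol genes (none higher and 21 lower of 23, -0.91, adjusted p = 9.6e-12) fell. STARD4 was at -2.23. OLAH rose by 6.13 and ANK2, an ankyrin, by 4.08, and IGFBP5 fell by 8.01. The genes called from 4 to 24 h numbered 8146 at 0.01 nM (3952 higher, 4194 lower), 9352 at 0.2 nM (4620 and 4732) and 12243 at 3 nM (6223 and 6020). The deeper 3 nM libraries allow smaller changes to be called. At least 2-fold, 1472, 2004 and 2994 genes changed at 0.01, 0.2 and 3 nM.

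The change from 4 to 24 h differed between 3 and 0.2 nM for 6527 genes (3512 higher and 3015 lower at 3 nM), of which 236 and 982 were at least 2-fold, against 3251 genes with limma on TPM. Inflammatory genes fell less at 3 nM (14 higher and 1 lower of 18, median difference 1.31, camera adjusted p = 3.8e-06): CXCL8 changed by -2.01 at 3 nM and by -5.44 at 0.2 nM (difference 3.43, SE 0.194, edgeR adjusted p = 1.3e-21). Ribosome biogenesis genes also differed (26 higher and none lower of 27, or 27 higher adjusted over the list alone, 0.395, adjusted p = 1.1e-13). HSPA5 differed by 0.56, TNFRSF10B by 0.58 and EIF2AK3 by 0.37.

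The untreated sets gave the background. All 13 mitochondrially encoded mRNAs were lower in set 2 than in set 1 (median -1.14, camera adjusted p = 1e-55), with MT-ND4 at -1.26 and MT-CYB at -1.21. Of 17 immediate early genes 15 were lower and none higher (-0.61, adjusted p = 5.7e-21), with FOS at -2.93 (SE 0.0855, edgeR adjusted p = 3.1e-35) and KLF2 at -1.54. Chaperones of the endoplasmic reticulum were lower in set 2 (none higher and 16 lower of 23, or 18 adjusted over the list alone, -0.20, adjusted p = 1.5e-11), with CALR at -0.40. On the TPM scale their median was 0.0085, and -0.21 relative to the median of all genes, which was 0.22 on that scale. KCNA1, a potassium channel gene, was higher in set 2 by 2.37 and PKNOX2, a homeobox gene, lower by 5.71. The test called 5215 genes between the sets (2684 higher and 2531 lower; 499 and 104 at least 2-fold), against 5657 higher and 262 lower with limma on TPM and 2126 and 3071 with DESeq2. The labels do not say how the sets differ. A count against untreated below 5215, such as the 5077 at 0.01 nM after 1 h, cannot be set apart from such a difference. The same holds for the 4843 at 3 nM after 1 h against set 2 and for the 4923 between 3 and 0.2 nM after 1 h. At least 2-fold, 603 genes differed between the sets, against 341, 359 and 271 at 0.01, 0.2 and 3 nM after 1 h. At 3 nM after 2 h the number was 561. A larger count may still hold such a difference in part.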

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

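The tests of the fall of immediate early genes were chosen only after the result was seen, and the tests on thinned libraries only after the depths of the libraries were seen. The rule for naming genes did not cover the comparison of the next paragraph, whose 10 genes were chosen after their values were seen.

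A test of the difference marked the dose by time comparison and the 5 largest rises and 5 largest falls in it, in which the change from 4 to 24 h differed between 3 and 0.2 nM. It called 6527 genes (edgeR, Benjamini-Hochberg), against 3251 with limma on TPM. The difference was 4.16 for ESM1, which is secreted by endothelium (2.63 at 3 nM and -1.53 at 0.2 nM, adjusted p = 2.9e-12), 4.14 for CSF2 (-5.06 and -9.20, adjusted p = 0.0412), 3.99 for TNF (-3.00 and -7.00, adjusted p = 0.0324), 3.66 for BCL2A1 (1.18 and -2.48, adjusted p = 1.1e-11) and 3.43 for CXCL8 (-2.01 and -5.44, adjusted p = 1.3e-21). CSF2 and TNF had no counts at 0.2 nM after 24 h, so their fitted values depend on the prior count and set no bound; from 4 to 24 h there they were at least 51.9-fold and 11.2-fold lower. It was -5.55 for RMRP (-5.29 and 0.26, adjusted p = 0.0265), -5.36 for RNA5S1 (-4.82 and 0.54, adjusted p = 0.0278), -5.18 for RNA5-8S5 (-4.44 and 0.74, adjusted p = 0.00021), -4.67 for TMEM37 (-3.87 and 0.81, adjusted p = 3e-12) and -5.31 for DRD1 (-7.19 and -1.88, adjusted p = 1.3e-08). DRD1 had 3 counts over the group at 3 nM after 24 h, 177-fold lower than after 4 h (95% counting interval 60.4 to 863), so its fitted values are imprecise. Its difference was -6.899 with the deep libraries thinned and -0.781 with limma on TPM. With limma on TPM the difference was smaller for TMEM37 (-2.053) and ESM1 (3.237) too, though both stayed called.

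Some of these values and calls changed when a single library was left out. Without replicate 1 at 3 nM after 4 h the difference was -4.818 for RMRP, -3.936 for RNA5S1 and -3.75 for RNA5-8S5 (adjusted p = 0.0265, 0.00372 and 7.07e-05). RMRP was at -6.18 without replicate 2 at 3 nM after 24 h, and lost its call without replicate 2 or 3 at 0.2 nM after 24 h, at values of -5.283 and -5.582 (adjusted p = 0.113 and 0.0716). RNA5S1 was at -6.022 without replicate 3 at 0.2 nM after 4 h, and lost its call without replicate 1 there (-4.735, adjusted p = 0.0558) and without replicate 1 or 2 at 0.2 nM after 24 h (-4.904 and -5.438, adjusted p = 0.157 and 0.0621). For CSF2 and TNF the call ended but the value hardly moved when any 1 of the 3 replicates at 0.2 nM after 24 h was left out (CSF2 4.146, 4.152 and 4.145, adjusted p = 0.103, 0.101 and 0.108; TNF 3.996, 4.001 and 3.995, adjusted p = 0.0856, 0.0833 and 0.0902). The calls also ended without replicate 2 at 3 nM after 24 h (CSF2 3.761 and TNF 3.711, adjusted p = 0.0855 and 0.0515), and at 0.2 nM after 4 h for CSF2 without replicate 3 (3.907, adjusted p = 0.0623) and for TNF without replicate 1 (3.692, adjusted p = 0.0633). They ended as well for TNF with DESeq2 (2.904, adjusted p = 0.0568) and without the filter (3.998, adjusted p = 0.0617), and for CSF2 with the deep libraries thinned (3.054, adjusted p = 0.0805). With limma on TPM both pointed the other way (-0.152 for CSF2, adjusted p = 0.852, and -1.093 for TNF, which was called, adjusted p = 0.00124).

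Immediate early genes were lower than untreated at every dose from 4 h on. After 1 h at 3 nM the list was higher instead (15 higher and 2 lower of 17, median 0.544). At 0.01 nM after 1 h its sign depended on the control, with a median of -0.275 against set 1 and 0.379 against set 2. Untreated set 1 cannot alone be the cause of the fall, since the median was -2.08 against untreated set 2 only at 3 nM after 24 h (spread of the median 0.636). The spread, here and below, was computed over the members of a list as if they were independent. Genes of a list can be regulated together, so it may understate the uncertainty. A fall that deepens with the dose is argued against by the median difference of -0.13 between 0.2 and 0.01 nM at 24 h (spread 0.284). The list was graded the other way at 4 h, with a median difference of 0.81 between 0.2 and 0.01 nM (spread 0.219) and 0.737 between 3 and 0.2 nM (17 of 17 genes higher), and it was higher by 0.69 at 3 than at 0.2 nM after 24 h (12 genes higher and none lower), or by 1.23 with each dose relative to its own untreated set. The last value also holds the lower level of the list in set 2 than in set 1 (median -0.608). A response to the drug that lessens the fall at higher doses stays open. Handling of the cells around drug addition or the untreated collection (time 0), such as a change of medium, may still account for it, since the median change from 4 to 24 h at 0.01 nM was -0.433 (spread 0.321), on neither side of the bound set for it.

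The untreated sets differed by 5215 genes. The greater number of reads in set 2 is argued against as the sole cause, as 4329 genes were called after the deep libraries were thinned to the depth of the others. Thinning cannot test any other difference of the deep libraries, since it keeps each gene's expected share of the counts. A library batch shared with the doses stays open: across 18040 genes, which are not independent, set 2 against set 1 and 3 against 0.2 nM at 1 h correlated with r = 0.17. No biological explanation was tested, since the labels give none.

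Inflammatory genes were higher at 3 than at 0.2 nM after 24 h. With each dose relative to its own untreated set the median difference was 1.81 (spread 0.475). This argues against a batch shared by the treated and untreated deep libraries. The subtraction cannot test a batch that acted on the treated libraries alone, and the labels tie no untreated set to a dose. After thinning the median difference was 2.43 (spread 0.452). Thinning leaves each gene's expected share of the counts unchanged, so the median was bound to stay close and cannot decide about depth. A response that lasts longer at the higher dose is a candidate explanation, as a hypothesis found and tested on the same data.

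Each count was compared with other splits of the same libraries, in fits of the compared libraries alone. Against untreated there were 84 splits. The real split called most genes at 2 h and later, with 1 split of 84 in each, so a chance assignment of these libraries could be excluded. At 0.01 nM it called 5093, 7229, 7434, 7281 and 4966, against 1790, 1192, 1069, 1020 and 1770 in the highest other split. At 0.2 nM it called 5436, 8722, 9603, 10164 and 9859 against 2269, 1127, 713, 524 and 601. At 3 nM it called 6288, 10390, 11997, 13112 and 13454 against 4016, 1668, 693, 292 and 315. Such splits cannot exclude a difference between sets of libraries that is unrelated to the drug. Between the untreated sets alone the same kind of fit called 4729 genes. At 1 h 3, 2 and 2 of the 84 splits gave as many genes as the real 1552, 2872 and 3649 at 0.01, 0.2 and 3 nM, and the highest other gave 1870, 2950 and 5450. That split set the 3 libraries of untreated set 1 apart from the rest, which points to a structure of the samples; against the untreated set of like depth 5111, 6434 and 4843 genes were called.

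For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For 3 against 0.2 nM the real split gave 4770, 5924, 6309, 6676, 8194 and 9911 and the highest other 0 at each time. For 0.2 against 0.01 nM it gave 62, 1295, 4232, 6277, 7671 and 8554, and the highest other 5, 1, 0, 0, 0 and 1. From 4 to 24 h it gave 7655, 8689 and 12622 at 0.01, 0.2 and 3 nM, and the highest other 0, 1 and 0; between the untreated sets it gave 4729, and the highest other 1. For the dose by time difference, 1 of 100 drawn splits, the real one, gave 6285 genes, and the highest other 4895. These draws shuffled the labels of all compared groups, which also broke up the effects of dose and of time. They therefore cannot decide about the dose by time difference itself. Nor can they exclude a difference between sets of libraries that is unrelated to the drug.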

How the results depend on the processing

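Most results kept their direction and their side of the threshold. Of the named gene results 745 stayed the same with DESeq2, 747 with RLE size factors, 741 with the deep libraries thinned, 732 without the filter, 657 with the compared samples only and 703 with limma on log2(TPM + 1), whose added 1 shrinks genes at low levels. Without 1 library at a time, 5841 gene results stayed the same, 61 were weaker and 8 stronger. A count of called genes was kept as the same when it lay within a tolerance of the main count, so its value could still change. In that sense all 35 counts stayed the same with RLE size factors, thinning and a replicate block. Between the untreated sets, for example, thinning took the count from 5215 to 4329. Replicate numbers did not pair the libraries, and with the block 5102 genes were called at 0.01 nM after 1 h.

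With limma on TPM 5179 and 5523 genes were called at 3 nM after 1 and 2 h, 1641, 3136, 3532, 3428, 4591 and 6434 between 3 and 0.2 nM after 1, 2, 4, 8, 16 and 24 h, 220 and 1098 between 0.2 and 0.01 nM after 1 and 2 h, and 3251 for the dose by time difference. Against untreated set 2 only 4843 were called at 3 nM after 1 h, and with each dose relative to its own set 2334, 4042, 4201 and 4586 between 3 and 0.2 nM after 1, 2, 4 and 8 h. Between 0.2 and 0.01 nM after 1 h DESeq2 called 312, no filter 248, the compared samples only 62, and leaving out 1 library 50 to 255 (255, 58 and 50 without replicates 1, 2 and 3 at 0.01 nM, 54, 88 and 78 without those at 0.2 nM). The cause was not tested.

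With an estimated correlation fewer gene lists were called: 10 of 19 at 0.01 nM after 4 h, 13 of 23 at 3 nM after 4 h, 11 of 21 at 0.2 nM after 24 h, 8 of 16 between 3 and 0.2 nM after 24 h, 6 of 13, 6 of 17 and 10 of 18 from 4 to 24 h at 0.01, 0.2 and 3 nM, 9 of 17 between the untreated sets and 7 of 18 for the dose by time difference. This setting widens the test by construction.

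Some results reversed, and the cause was not tested. Against untreated set 2 only, PPP1R15A was at 0.027 and GDF15 at 0.096 at 0.2 nM after 4 h, CEBPB at 0.127 at 0.01 nM after 24 h, and the mitochondrially encoded mRNAs at 0.106 and 0.093 at 0.01 nM after 4 and 24 h. Against untreated set 1 only, CEBPB was at -0.07 at 0.01 nM after 4 h. With limma on TPM, DDIT4 was at 0.042 between the untreated sets, CEBPB at 0.008 at 0.01 nM after 24 h, VEGFA at 0.05 at 0.2 nM from 4 to 24 h and EIF2AK4 at 0.005 at 3 nM after 24 h, and the dose by time difference was -0.152 for CSF2 and -1.093 for TNF. With each dose relative to its own set, 3 against 0.2 nM gave 0.055 for VEGFA, 0.148 for GDF15, -0.054 for SLC7A11 and 0.222 for HSPA5 after 4 h, and 0.395 for GDF15 after 24 h.

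Depth limits genes at low levels, for which bounds or counting intervals are given where a group had 3 counts or fewer, and 3 libraries in each group leave 10 splits for direct comparisons.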

Other observations

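The abundance of short structural RNAs was uneven between replicates at 3 nM. RNA5-8S5, the 5.8S ribosomal RNA, stood at 135, 118 and 513 CPM in the 3 libraries after 2 h and at 1340, 204 and 230 CPM after 4 h, against 14.3 to 42.7 CPM in the untreated libraries.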
